A study of Mus musculus with 8 samples.

How the data were processed

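Total RNA from the right cranial lobes of 4 control and 4 naphthalene-injected mice was sequenced from stranded total RNA libraries, after DNase digestion, per the labels' protocols. The authors deposited whole-number read counts per gene symbol, with a different total in each library and no normalisation. Trim Galore 0.6.7, HISAT2 2.2.1, featureCounts 2.0.6, edgeR 4.2.1 and the build mm39 are named per the submitters' processing notes, without role or order. The gene annotation, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Values are therefore uncertain for genes with near-identical copies, such as the haemoglobin genes Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, the glutathione transferase genes, the Serpina3 cluster and the mucins, and for overlapping or antisense genes.

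Columns were assigned to mice by the library names in the labels, and 0 columns belonged to other samples. Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr (minimum count 10, minimum total 15) and the quasi-likelihood test with group as the only term. P values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Levels are CPM with TMM scaling, and standard errors of log2 fold changes are those of the difference in group means of log2 CPM with a prior count of 2. Gene lists for cell types, processes, tissue handling, sampling time and systemic stress were tested with camera in limma 3.58.1 at a preset correlation of 0.01, where at least 5 members were tested, and again with an estimated correlation and with fry. Group separation was measured on the 500 genes of largest variance over the 35 splits of the libraries, and library measures by exact 2-sided permutation.

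The comparison, tests, gene lists and most alternatives were chosen before the data were examined. Named genes were the 10 higher and 10 lower genes of largest change among those past the threshold with a mean CPM of at least 1 in the higher group and no overlap between groups, 13 fixed genes, and up to 4 members of each list with the smallest p among those past the test, or up to 2 where none passed. Unnamed gene models were left out, which removed 1 gene with as large a change. Genes named only in the closing section were chosen after their values were seen. Some list members, among them immunoglobulin and T cell receptor constant genes, were not matched by symbol and were not analysed here. Results for a few single genes are not reported here.

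The 12 pairs of libraries within groups differed by a chi-square per degree of freedom of 5.75 to 51.2, far above sampling noise, so each library was counted once. Total counts ranged from 10743842 to 16792306, and a floor of 3 counts over the control group corresponds to 0.0597 CPM. The procedure was tested on simulated data for naphthalene against control with 200 changed genes, of which those tested gave the following recoveries among 13981 tested genes. At a log2 change of 1 it recovered 80% of 50 genes, at -1 68.1% of 47, at 2 100% of 50 and at -2 95.7% of 46, with 9 false calls among 194. Simulating a shift of 0.8 in 1 list called that list and 0 of the others. Genes were simulated independently of each other, whereas the estimated correlation within lists reached 0.783 in the data (endothelial list). The simulation therefore gives no measure of false list calls here.

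Alternatives covered RLE and upper quartile scaling, no filter, a stricter filter (CPM of 1 in 4 libraries), a replicate block, each library left out, voom with and without quality weights, robust estimation, a minimum fold change, removal of mitochondrial and haemoglobin genes, 1 surrogate variable (sva 3.50.0) and DESeq2 1.42.0. A correction for transcript length and GC content, and the removal of control 3 with naphthalene 1, were added after seeing the data. Names, gene order, lengths and GC content came from GENCODE M21 and a RefSeq table on GRCm38, another build than that of the counts, so no coordinates are given. Of 22244 symbols, 20467 matched the RefSeq table directly and 98 through a synonym, leaving 1679 unmatched.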

Results

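Lung RNA was profiled in adult male C57BL/6J mice, a standard inbred strain, that had been injected with naphthalene or left as controls. Naphthalene is an aromatic hydrocarbon that club cells of the mouse airway convert to toxic metabolites through cytochrome P450 enzymes, and it is used as a model of airway epithelial injury. Each library came from the right cranial lobe of a separate mouse, with 4 control and 4 naphthalene libraries. The labels describe the control mice as untreated, and the dose, the vehicle and the time from injection to sampling are not given in the sources used here. Effects of the injection or vehicle therefore cannot be separated from those of naphthalene in any comparison below. Total counts ranged from 10743842 to 16792306 per library. Of 22244 genes in the table, 14192 had enough counts to be tested.

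The comparison asked which genes differ between naphthalene-injected and control lungs. Most tested club cell, ciliated cell and T, NK and B cell genes were lower after naphthalene (19 of 19, 21 of 22, 12 of 15, 11 of 12 and 11 of 11), whereas most tested oxidative stress, protein folding stress, glucocorticoid-responsive and damage-associated epithelial genes were higher (20 of 24, 13 of 17, 13 of 13 and 13 of 17). As lists these passed limma's camera test with its preset correlation between genes, but no list passed with an estimated correlation (smallest adjusted p = 0.107). Scgb1a1, the secretoglobin that marks club cells, fell from 4785 ± 1564 to 1325 ± 643 CPM (counts scaled to library size; mean ± SD, n = 4 per group), a log2 fold change of -1.85 (SE 0.42, edgeR quasi-likelihood adjusted p = 0.00207). Cyp2f2, the P450 that activates naphthalene in club cells, fell from 1274 ± 394 to 207 ± 71.1 CPM. In the other direction, Cdkn1a, a cell cycle inhibitor, rose from 12.98 ± 2.22 to 62.3 ± 24.1 CPM and Saa3, a serum amyloid gene, rose from 0.684 ± 0.176 to 12.8 ± 3.79 CPM. In total 4075 genes (28.7% of those tested) passed an adjusted p of 0.05, 2005 higher and 2070 lower, and of these 402 higher and 776 lower genes also changed by a log2 value of at least 1. The 4 control and 4 naphthalene values did not overlap for 4059 genes, or 28.6% of genes against 2.86% by chance. Libraries separated by group on the first principal component, which held 62.6% of the variance, and between-group distances exceeded within-group distances by 33.9 on the log2 CPM scale (exact permutation p = 0.0286, 1-sided, the smallest that 35 splits allow).

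**Figure D1:**
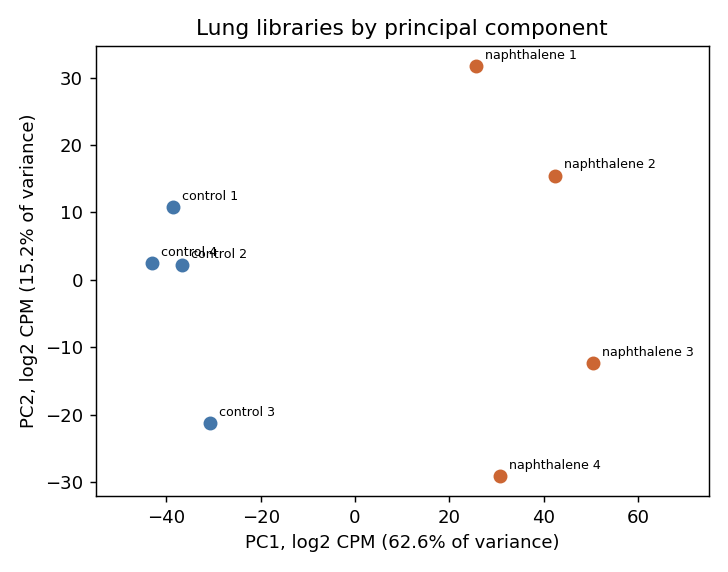
The first 2 principal components of log2 CPM, with the share of variance on each axis label, for 4 control (blue) and 4 naphthalene (orange) libraries, 1 point per mouse. The groups lie on opposite sides of the first component, which holds 62.6% of the variance, while the second holds 15.2%.

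Club cell genes were lower throughout. All 19 tested members of the club cell list fell, and 19 passed when adjusted over the list alone, with a median log2 fold change of -2.30. Members with the smallest p were Muc5b, an airway mucin (206 ± 68.4 to 14.9 ± 4.02 CPM), Cckar, Cyp2f2 (log2 fold change -2.62, SE 0.33) and Gabrp (116 ± 32.1 to 14.6 ± 7.56 CPM). The club secretoglobin Scgb3a2 also fell, by 2.30 on the log2 scale (SE 0.54). The list passed limma's camera test (adjusted p = 3.06e-11), with adjusted p = 0.199 with an estimated correlation. Of 14 tested phase I xenobiotic metabolism genes, 8 fell and 2 rose, and 12 passed when adjusted over the list alone. Cyp1a1 fell by 1.48, Cyp2s1 by 1.96 and the carboxylesterase Ces1d by 0.84 on the log2 scale (camera adjusted p = 0.0115, and adjusted p = 0.326 with an estimated correlation). Among 7 tested mucous cell genes 3 fell, namely Muc5b, Muc5ac and Fcgbp. When adjusted over the list alone 6 passed, 5 lower and 1 higher (camera adjusted p = 0.00648, and adjusted p = 0.199 with an estimated correlation). Over all genes 5 mucous cell genes passed without naphthalene 1, 2 or 4 and 6 without control 3.

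Genes of motile cilia were lower as well. In the ciliated cell list 21 of 22 tested members fell, also 21 when adjusted over the list alone, with a median log2 fold change of -2.02. They included Dnah5, an outer dynein arm heavy chain (275 ± 63.1 to 35.5 ± 15.1 CPM), Hydin, a central apparatus component (100.05 ± 28.5 to 16.0 ± 2.83 CPM), Cdhr3 and Ak7. The exception was Foxj1, the transcription factor of motile ciliogenesis, at 52.8 ± 15.8 and 32.7 ± 20.9 CPM (log2 fold change -0.68, SE 0.48, edgeR adjusted p = 0.188), and without naphthalene 1 its log2 fold change was -1.20 with adjusted p = 0.0045. Foxj1 also passed as lower with the replicate block, quality weights, 1 surrogate variable and the length and GC correction, and without control 3 and naphthalene 1 together. Of 10 tested genes of commitment to the multiciliated state 5 fell, and 6 passed when adjusted over the list alone. Those 5 included Gmnc and Myb, which fell by 3.03 and 2.78 on the log2 scale. Both lists passed camera (adjusted p = 1.02e-14 for ciliated cells and 0.000689 for commitment), each with adjusted p = 0.199 with an estimated correlation. Among 7 tested neuroendocrine genes Uchl1 and Calca rose and Piezo2 fell, 3 passing also when adjusted over the list alone. Piezo2 lost its call without any 1 of 7 of the 8 libraries (adjusted p 0.0648 to 0.107). The neuroendocrine list had a median of -0.03, a mean of 0.60 and an upward camera direction that did not pass (adjusted p = 0.499). The basal cell list had 4 tested members and was not tested as a list. The basal keratin Krt5 was too low to test, with 13, 2, 1 and 5 counts in controls and 7, 1, 9 and 27 after naphthalene.

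**Figure D2:**
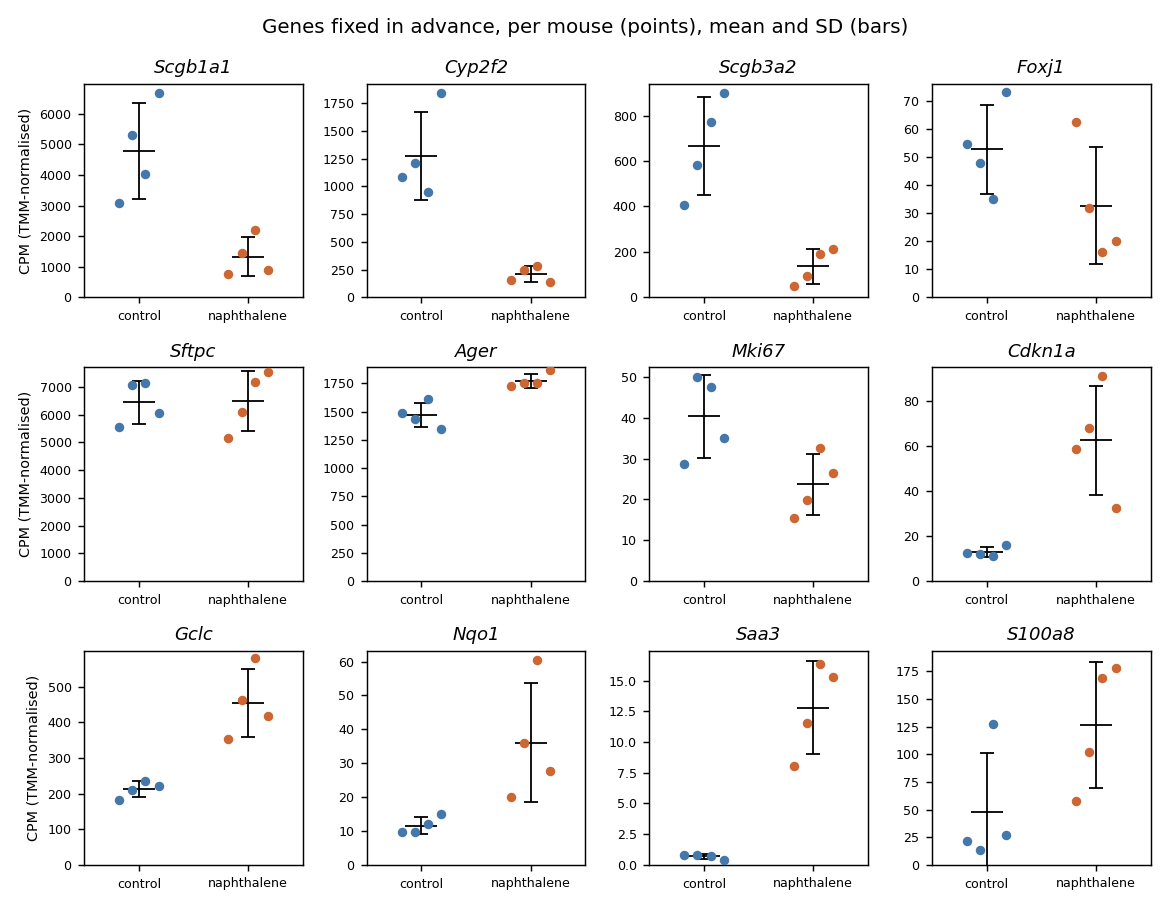
TMM-normalised CPM (vertical axes, each starting at 0) of 12 fixed genes in control and naphthalene lungs; points are mice, and the horizontal mark and bar give the mean and SD of 4. Scgb1a1, Cyp2f2 and Scgb3a2 are lower and Cdkn1a, Gclc, Nqo1 and Saa3 higher in all 4 naphthalene mice than in any control mouse. Ager, which did not pass the threshold, is also higher in all 4.

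Most alveolar epithelial genes past the threshold rose. The surfactant gene Sftpc stood at 6452 ± 778 and 6502 ± 1081 CPM (log2 fold change 0.01, SE 0.15, edgeR adjusted p = 0.965). Of 19 tested alveolar type 2 genes 7 rose and 2 fell, 9 passing also when adjusted over the list alone. Ctsh, Il33 and Napsa rose by 1.47, 0.85 and 0.60 on the log2 scale, while the complement gene Hc fell by 1.17. That list did not pass camera (adjusted p = 0.0864), but it did without control 3 (0.0432) or naphthalene 1 (0.0305). Of 16 tested alveolar type 1 genes 7 rose. When adjusted over the list alone 10 passed, 9 higher and 1 lower (camera adjusted p = 0.00441, and adjusted p = 0.392 with an estimated correlation). Without control 4 the number past the threshold was 4. Krt7, Lmo7 and the type 1 membrane protein Pdpn rose by 1.47, 0.77 and 0.61 on the log2 scale. The type 1 marker Ager was at 1472 ± 109.8 and 1775 ± 62.6 CPM (edgeR adjusted p = 0.0643), with no overlap between groups. It passed without control 3 (adjusted p = 0.0455) and without control 3 and naphthalene 1 together. Ager also passed with voom, with quality weights, with 1 surrogate variable and with DESeq2. Of 17 tested genes of the transitional, damage-associated alveolar state 13 rose and 1 fell, and 15 passed when adjusted over the list alone. The tight junction gene Cldn4 rose from 3.26 ± 0.774 to 28.4 ± 8.62 CPM, the growth factor genes Areg and Hbegf rose by 2.80 and 1.503 on the log2 scale, and Lcn2 rose by 2.23 (camera adjusted p = 3.7e-07, and adjusted p = 0.199 with an estimated correlation).

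Stress response genes rose. Of 24 tested targets of NRF2, the transcription factor of the oxidative stress response, 20 rose, also 20 when adjusted over the list alone. Slc7a11, the cystine transporter, rose from 8.21 ± 2.04 to 63.6 ± 25.7 CPM, and the haem oxygenase gene Hmox1 rose by 1.86, Txnrd1 by 1.14 and Gstp1 by 1.13 on the log2 scale. Gclc, which encodes the catalytic subunit for glutathione synthesis, rose from 212 ± 22.2 to 454 ± 95.5 CPM, and Nqo1 rose by 1.63 on the log2 scale (camera adjusted p = 3.11e-09 for the list, and adjusted p = 0.283 with an estimated correlation). Of 17 tested unfolded protein response genes 13 rose, also 13 when adjusted over the list alone, among them Manf, Xbp1, Atf4 and Ddit3 with log2 fold changes of 0.58 to 0.82 (camera adjusted p = 3.26e-07, and adjusted p = 0.107 with an estimated correlation). Of 20 tested p53 targets 7 rose, also 7 when adjusted over the list alone, including Cdkn1a, Fas, Aen and Sesn2 (camera adjusted p = 0.00441, and adjusted p = 0.257 with an estimated correlation). All 13 glucocorticoid-responsive genes rose, also 13 when adjusted over the list alone, with Mt2 from 2.74 ± 1.06 to 36.7 ± 15.1 CPM and Pdk4 and Sult1a1 by 2.26 and 1.34 on the log2 scale (camera adjusted p = 1.54e-10, and adjusted p = 0.199 with an estimated correlation).

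T, NK and B cell genes fell. Of 15 tested T cell genes 12 fell, and 15 passed when adjusted over the list alone, with Themis, Bcl11b and Lef1 lower by log2 values of -1.60, -1.43 and -1.40. Of 12 tested NK cell genes 11 fell, also 11 when adjusted over the list alone, with Ncr1 from 7.03 ± 0.812 to 1.54 ± 0.692 CPM. All 11 tested B cell genes fell, also 11 when adjusted over the list alone, with Fcer2a and Bank1 lower by log2 values of -1.64 and -1.56. The lists passed camera with adjusted p = 9.66e-08 for T cells, 3.7e-07 for NK cells and 1.53e-07 for B cells. T and NK cells each had adjusted p = 0.199 with an estimated correlation, and B cells had adjusted p = 0.257 with an estimated correlation. Of 5 tested plasma cell genes 3 fell, including Jchain, and Sdc1 rose, 4 passing also when adjusted over the list alone (camera adjusted p = 0.229). Of 20 tested interferon-stimulated genes 10 fell, and 12 passed when adjusted over the list alone, 11 lower and 1 higher. Ifi44, Gbp3 and Oas1a were lower by log2 values of -1.41, -1.38 and -1.16 (camera adjusted p = 0.00404, and adjusted p = 0.385 with an estimated correlation). The number of interferon-stimulated genes past the threshold was 5 without control 1 and 6 without control 3, control 4 or naphthalene 3.

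Several inflammatory mediators rose. Of 15 tested cytokine and chemokine genes 8 rose, also 8 when adjusted over the list alone. The monocyte chemoattractant Ccl2 rose from 0.542 ± 0.199 to 5.83 ± 2.63 CPM, and Ccl7, Il6 and Il11 rose by 3.32, 2.95 and 1.75 on the log2 scale (camera adjusted p = 0.000271, and adjusted p = 0.199 with an estimated correlation). Of 12 tested acute phase genes 4 rose and 2 fell, and 7 passed when adjusted over the list alone, with Saa3, Orm1, Lcn2 and Lrg1 rising by 4.21, 2.42, 2.23 and 1.53 on the log2 scale (camera adjusted p = 0.412). Of 12 tested type 2 immunity genes 5 rose and 1 fell, and 8 passed when adjusted over the list alone (camera adjusted p = 0.144), with Ccl17 higher by 1.92 and Retnla lower by a log2 value of -1.58. Of 13 tested neutrophil genes 3 rose, and 2 passed when adjusted over the list alone (camera adjusted p = 0.0383, and adjusted p = 0.544 with an estimated correlation). The neutrophil call was lost without control 1, control 2, naphthalene 3 or naphthalene 4 (adjusted p 0.0601 to 0.149). The 3 genes became 1 without control 1, 2 or 4 or naphthalene 2 or 3, 10 without control 3 and 5 without naphthalene 1. Control 3 held more S100a8, a neutrophil calprotectin gene, than the other controls (127.5 CPM against 13.2 to 27.4). S100a8 did not pass at 47.5 ± 53.7 and 127 ± 57.0 CPM (log2 fold change 1.42, SE 0.80, edgeR adjusted p = 0.108), and passed without control 3 (log2 fold change 2.60, adjusted p = 0.00142) or naphthalene 1 (1.66, adjusted p = 0.0489). Of 20 tested monocyte and macrophage genes 4 rose and 3 fell, and 8 passed when adjusted over the list alone, with Trem2 higher by 1.21 and Csf1r lower by a log2 value of -0.86 (camera adjusted p = 0.469). Those past the threshold numbered 4 without control 2 or naphthalene 2 and 3 without naphthalene 3. Of 16 tested alveolar macrophage genes 1 rose and 2 fell, including Itgax at a log2 value of -0.76, with 3 passing when adjusted over the list alone (camera adjusted p = 0.697). Without naphthalene 1 the number past the threshold was 6, and the 1 that rose lost its call without control 1, 3 or 4 or naphthalene 3 or 4 (adjusted p 0.0602 to 0.0828), as did 1 of the 2 that fell without control 2 (0.0553).

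Stromal and matrix genes went both ways. Of 17 tested fibroblast genes 7 fell, and 8 passed when adjusted over the list alone, with Scube2 from 74.97 ± 4.87 to 19.3 ± 4.85 CPM and Fgfr4, Clec3b and Npnt lower by log2 values of -1.57, -1.16 and -0.84 (camera adjusted p = 0.00333, and adjusted p = 0.283 with an estimated correlation). Of 21 tested matrix and fibrotic repair genes 8 rose and 1 fell, and 10 passed when adjusted over the list alone. The protease inhibitor gene Timp1 rose from 3.88 ± 0.893 to 43.2 ± 6.88 CPM, and Vcan and Tnc rose by 2.04 and 1.54 on the log2 scale (camera adjusted p = 0.00813, and adjusted p = 0.283 with an estimated correlation). Of 18 tested endothelial genes 2 fell, also 2 when adjusted over the list alone, and they included Aplnr at a log2 value of -1.94 (camera adjusted p = 0.0413, and adjusted p = 0.667 with an estimated correlation). Of 10 tested smooth muscle genes 2 fell, also 2 when adjusted over the list alone, and they included Synpo2 at a log2 value of -1.21 (camera adjusted p = 0.0413, and adjusted p = 0.541 with an estimated correlation). The endothelial call was lost without control 1, control 2, naphthalene 3 or naphthalene 4 (adjusted p 0.0735 to 0.302). Endothelial genes past the threshold numbered 1 without control 2 or naphthalene 3 and 11 without naphthalene 1. The smooth muscle call was lost without those 4 or control 4 (adjusted p 0.0557 to 0.149). Smooth muscle genes past the threshold numbered 1 without control 1 or 2 or naphthalene 2 or 3, and 6 without naphthalene 1. Of 10 tested mesothelial genes 2 fell, including Lrrn4, also 2 when adjusted over the list alone. That list did not pass (camera adjusted p = 0.119), but it did without control 3 (0.0213). Its genes past the threshold numbered 1 without control 1 or 2 or naphthalene 2 or 3, 5 without control 3 and 4 without naphthalene 4. Of 10 tested YAP targets Ankrd1, Ccn2 and F3 rose, and 4 passed when adjusted over the list alone (camera adjusted p = 0.0864).

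Signalling and cell cycle genes changed in part. Of 23 tested Wnt, FGF, Hedgehog and Notch genes 8 fell and 3 rose, and 14 passed when adjusted over the list alone, with Wnt2, Shh and Ptch1 lower by log2 values of -1.01, -0.90 and -0.52 (camera adjusted p = 0.0413, and adjusted p = 0.516 with an estimated correlation). That call was lost without control 1, control 2, control 4, naphthalene 3 or naphthalene 4 (adjusted p 0.0505 to 0.141). Without naphthalene 1 the genes past the threshold numbered 17. Of 24 tested G2/M genes 5 fell, also 5 when adjusted over the list alone, including the mitotic kinesin gene Kif11 and the kinase gene Cdk1 (camera adjusted p = 0.00479, and adjusted p = 0.516 with an estimated correlation). The number past the threshold was 2 without control 2 and 3 without control 3 or naphthalene 2. The proliferation marker Mki67 fell from 40.4 ± 10.2 to 23.7 ± 7.55 CPM (edgeR adjusted p = 0.0291), and did not pass without control 2, control 3 or naphthalene 2 (adjusted p 0.0685 to 0.0877). Of 26 tested S phase genes only Pcna rose, and 0 passed when adjusted over the list alone (camera adjusted p = 0.0413, and adjusted p = 0.541 with an estimated correlation). Pcna did not pass without control 1, control 4 or naphthalene 3 (adjusted p 0.0533 to 0.0662), and the S phase list did not pass without those 3 or naphthalene 4 (adjusted p 0.0505 to 0.217). Without naphthalene 1, 3 S phase genes passed. Of 14 tested clock genes 3 rose and 3 fell, and 8 passed when adjusted over the list alone, with Cry1 higher by 1.17 and Nr1d1 lower by a log2 value of -1.55. The clock list had a median of 0.03, a mean of -0.07 and an upward camera direction that did not pass (adjusted p = 0.938). Of 14 tested immediate-early genes 3 rose and 2 fell, also 5 in all when adjusted over the list alone (camera adjusted p = 0.52). Without control 4 or naphthalene 2 the number past the threshold was 3. Of 20 tested lipid synthesis genes 1 rose and 1 fell, the latter being Scd1, also 2 when adjusted over the list alone (camera adjusted p = 0.547). Without control 3 the number was 4.

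Transcripts of tissue that can be carried over showed no list call. Of 14 tested cardiac muscle genes 0 passed in edgeR, over all genes or adjusted over the list alone, while 2 had an unadjusted p under 0.05, 1 passed in DESeq2 and 0 in voom, with a median of -0.12, a mean of -0.10 and an upward camera direction (adjusted p = 0.938). Without control 3 Actc1 and Ryr2 passed, lower by log2 values of -0.997 and -0.636 (adjusted p = 0.0048 and 0.0098). Of 9 tested red cell and platelet genes 0 passed in edgeR, likewise adjusted over the list alone, while 1 had an unadjusted p under 0.05, 1 passed in DESeq2 and 0 in voom (camera adjusted p = 0.385). Without naphthalene 1 or naphthalene 3, 1 passed, in the former case Pf4 (log2 fold change 1.11, adjusted p = 0.0158). Of 7 tested adipose genes 1 rose, also 1 when adjusted over the list alone (camera adjusted p = 0.938), and 0 passed without control 2 (adjusted p = 0.0645). Across the 40 lists, 39 could be tested and 24 passed camera with its preset correlation, 10 higher and 14 lower. None of the 24 calls held with an estimated correlation, where 9 lists had an unadjusted p under 0.05. The rotation test fry, which asks whether genes of a set move without comparing them with other genes, called 24 lists in 1 direction, 19 of them among the 24 that passed camera, and 33 in either.

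**Figure D3:**
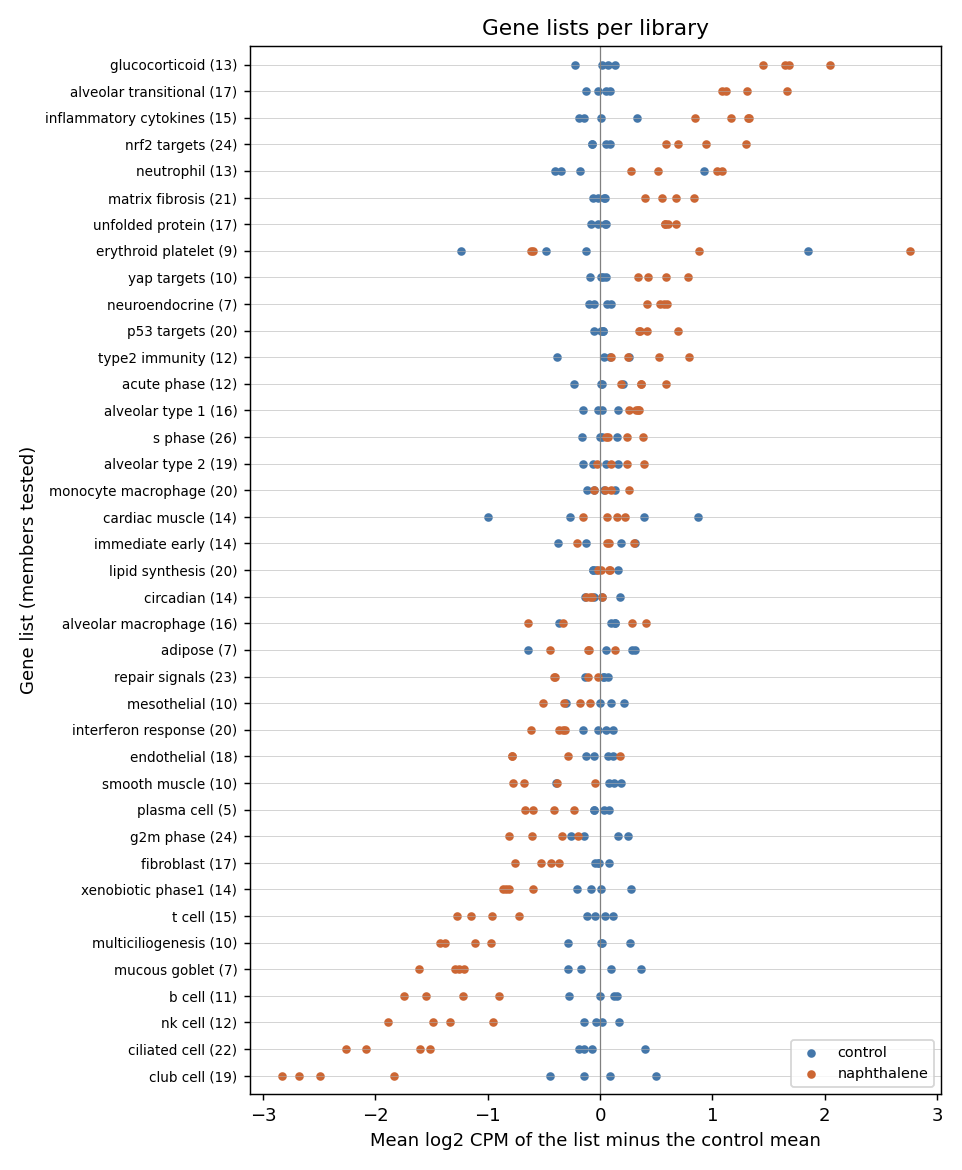
Mean log2 CPM of each of 39 gene lists minus the control mean (horizontal axis), 1 point per library, with the number of tested members in brackets; control libraries are blue and naphthalene libraries orange. Averaged over the 4 naphthalene libraries, club and ciliated cell lists lie lowest and glucocorticoid and transitional alveolar lists highest. Single libraries can differ, with the red cell and platelet list highest in naphthalene 3.

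The largest increases by rule were in genes nearly silent in control lungs. Mroh4, Fgf23, a phosphate-regulating hormone gene, Muc3 and the glycine receptor gene Glra1 had 0 control counts. Against a floor of 3 counts over the control group they were 48.3-fold, 38.5-fold, 29.6-fold and 23.1-fold higher. The lower 95% counting limits of their ratios were 38.9, 30.8, 23.6 and 18.3. The homeobox gene Bsx had 2 control and 312 naphthalene counts, a ratio of 144 with a 95% counting interval of 39.6 to 1195. Ratios were 136 for Stpg3 (24.0 to 5399), 93.3 for Trim38 (16.4 to 3721), 59.1 for Slc17a3 (16.0 to 493) and 72.0 for Gulo (12.6 to 2882). Syt8 rose from 0.0945 ± 0.0680 to 8.63 ± 5.05 CPM. The largest decreases were in Calml3 (6.71 ± 1.96 to 0.194 ± 0.235 CPM), Tbata, Ccdc153 (52.3 ± 11.6 to 2.54 ± 1.18 CPM), Ankrd65, Ldlrad1, T2, Uox, Muc5b, Lrrc74b and Gsg1l, with log2 fold changes of -5.24 to -3.69. Counting intervals and floors cover counting error only. In gene order Arc, next to Mroh4, rose by 3.84 on the log2 scale, and Slc17a2, between Trim38 and Slc17a3, rose by 2.13. A tested neighbour of Bsx, Glra1, Stpg3 and Syt8 rose by 0.32 to 0.88, whereas those of Fgf23, Muc3 and Gulo and the other neighbours of Trim38, Stpg3 and Syt8 did not pass. Muc3 belongs to a family of mucin genes with repetitive sequence, so its count is uncertain.

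Naphthalene libraries held counts for more genes, with 17193.5 ± 494 genes at a count of at least 1 against 16235.5 ± 42.7 in controls (exact permutation p = 0.0286, 2-sided, the smallest possible, and 0.171 adjusted over 6 measures). At a count of at least 10 the numbers were 14214.75 ± 150.1 and 14121.5 ± 163 (exact permutation p = 0.457). Total count, the share of the 10 most abundant genes, and mitochondrial and haemoglobin shares had an adjusted exact permutation p of 0.686, and the scaling factor had 0.257.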

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

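The tests weighed here were chosen after the result was seen, except the count over other splits of the libraries; for the length and GC test only the bound was set before its value was seen. A library far from the other 3 of its group (gap over range above Dixon's 95% critical value) was found in 27 of 394 groups of values, where chance gives about 1 in 20, or 19.7. Control 3 was the distant library 8 times, the most of any. It was high for the neutrophil genes S100a8 (ratio 0.8756, 127.5 CPM against 13.2 to 27.4), Retnlg (0.9323) and Clec4d (0.894) and for the neutrophil list (0.8364), high for Vcan (0.8738) and the lipid synthesis list (0.8825), and low for Cyp1a1 (0.8633). Control 4 was high for Cdhr3 (0.8707), Dnah5 (0.873), Egr3 (0.8667) and the haemoglobin share of counts (0.9341, 0.126% against 0.00238% to 0.0105%), and low for Ptch1 (0.9671). Control 1 was low for Gmnc (0.8857), Atf4 (0.8292) and the alveolar macrophage list (0.9345), and control 2 was low for Csf1r (0.866) and Per1 (0.8646). Naphthalene 1 was high for Ankrd65 (0.8597), naphthalene 3 low for Wnt2 (0.8718) and the interferon list (0.839), and naphthalene 4 high for Pdpn (0.8453) and low for Xbp1 (0.831) and Klf4 (0.9056). In Stpg3, Trim38, Slc17a3 and Gulo 1 control library held every control count, 1 or 2 in number, which gives a ratio of 1 by construction.

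The number of genes past the threshold was set against other splits of the libraries. Of 35 splits into 4 and 4, only 1, the real one with 4075 genes, gave as many, and the highest of the others gave 0. The real split thus ranked first, at the smallest share that 35 splits allow. Every other split mixed control and naphthalene libraries, so a difference between the groups widens the spread within it. The 0 calls there therefore cannot exclude chance.

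The club and ciliated lists were lower after naphthalene. After correction for transcript length and GC content the higher of their median changes was -1.853 log2 CPM, for ciliated genes, so length and GC bias is not the whole cause. Less airway in the sampled lobes stays open, because the club minus ciliated level per library (1.04 ± 0.182 in controls, 0.440 ± 0.451 after naphthalene) gave an exact permutation p of 0.08571. A loss of airway epithelial cells after naphthalene may account for the pattern as a hypothesis, and cannot be told apart from sampling of less airway in these data.

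The T, NK and B cell lists were lower after naphthalene, with a median log2 change of -1.30 over 38 genes. Dilution by RNA of cells outside the alveolar, endothelial and lymphocyte lists would lower all of these lists alike. The mean alveolar and endothelial level minus that of lymphocytes shifted by 1.289 log2 units (exact permutation p = 0.0286, the smallest possible). This argues against such dilution as the whole cause. Within that mean the endothelial list had a median log2 fold change of -0.26 and the alveolar type 1 and 2 lists of 0.33 and 0.24. Dilution by alveolar RNA was not tested. For less blood in the lobes, haemoglobin transcripts changed by 0.9786 log2 units. The 95% interval of -3.50 to 5.46 also holds the lymphocyte change, so the group change cannot decide. The red cell and platelet list averaged 6.10 and 4.22 log2 CPM in naphthalene 3 and 4. It averaged 2.10, 3.21 and 2.86 in controls 1, 2 and 3. T cell levels were 1.63 and 1.82 against 2.74, 2.90 and 2.66, and NK and B cell levels were likewise lower. Naphthalene 3 and 4 thus argue against less blood as the whole cause in those libraries. In the other direction, the red cell list averaged 5.19 in control 4 and 2.74 and 2.72 in naphthalene 1 and 2. The levels in naphthalene 1 and 2 lie within the range of controls 1, 2 and 3, however. T cell levels were 2.06 and 1.51 in naphthalene 1 and 2, and NK and B cell levels were likewise lower than in those controls. The T cell level of control 4 was 2.83, near the 2.74 of control 1, despite its higher red cell level. Glucocorticoid exposure could lower lymphocyte numbers, and 4 of 4 genes examined (Fkbp5, Tsc22d3, Zbtb16 and Per1) were higher. These 4 belong to the 13 glucocorticoid-responsive genes already seen to be higher, so they add no separate support. A role of glucocorticoids remains a hypothesis, since treatment and any stress of injection fall on the same mice.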

How the results depend on the processing

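The length and GC correction and the removal of control 3 with naphthalene 1 were added after seeing the data. Against 4075 genes in the analysis as reported, voom with quality weights called 6503 (3186 higher, 3317 lower), and a test against a log2 fold change of 1 called 361 (130 higher, 231 lower) with 59 list members against 267, as a test with a minimum change must call fewer. The length and GC correction gave 3278 higher genes against 2005 (59.0% higher against 49.2%), and 7 of the calls tested there reversed; the cause was not tested. With an estimated correlation camera called 0 lists against 24, while 9 had an unadjusted p under 0.05 and fry called 24 in 1 direction. Of these 19 were camera calls; fry lost endothelial, smooth muscle, neutrophil, G2/M and S phase and gained neuroendocrine, plasma cell, acute phase, type 2 immunity and YAP targets. Leaving out 1 library gave 2929 to 5058 genes (1397 to 2465 higher, 1513 to 2593 lower), 19 to 26 lists and 234 to 311 list members. Counts were 4593 with DESeq2, 4104 with voom, 4074 with RLE scaling, 3958 with upper quartile scaling, 4034 without a filter, 4038 with a stricter one, 5853 with 1 surrogate variable and 5349 without control 3 and naphthalene 1. Replicate numbers did not pair the mice: deviations of same-numbered libraries correlated at -0.09 to 0.29, and 3 of 8 libraries correlated best with their own number. A replicate block gave 4363 genes, with 3865 of the 4075 kept, and changed 0 list calls, while Foxj1, S100a8 and Pf4 passed under it. Outside the test with a minimum change, 131 of 154 named genes kept their side of the threshold in each setting that tested them (the stricter filter left out Glra1, Gulo, Slc17a3 and Uox, and the fits without naphthalene 1 or 2 left out Glra1 and Gulo), 16 lost it and 7 gained it in at least 1, and 0 reversed. Smooth muscle also lost its list call with upper quartile scaling and the stricter filter, matrix and G2/M without control 3 and naphthalene 1, neutrophil, S phase and repair signals with the length and GC correction, S phase and repair signals with quality weights, and S phase without a filter. Alveolar type 2 gained a call without control 3 and naphthalene 1, mesothelial without a filter and with quality weights, and YAP targets with quality weights and the length and GC correction. Depth limits genes at a few counts, such as Krt5.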

Other observations

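All genes and gene families in this paragraph and the next were chosen or grouped after the data were seen. The EGF receptor ligand gene Ereg rose from 0.431 ± 0.248 to 16.1 ± 2.41 CPM (n = 4 per group, edgeR adjusted p = 2.22e-06), the ligand genes Areg, Hbegf and Tgfa rose by 2.80, 1.503 and 0.43 on the log2 scale, Btc fell by 0.97, and Egf did not pass (adjusted p = 0.280). The protease inhibitor gene Serpina3n rose from 37.3 ± 8.42 to 396 ± 62.8 CPM, the alkaline phosphatase gene Alpl rose by 3.49 and Angptl4, a lipoprotein lipase inhibitor, by 2.53 on the log2 scale. The metal-handling genes Mt1 and Slc39a14 rose by 2.18 and 2.002 on the log2 scale.

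Genes sharing a symbol stem with at least 8 tested members were tested with camera. Of 246 families 16 were higher and 13 lower, and 0 passed with an estimated correlation. Cilia and flagella associated genes (Cfap, 29 of 41 members lower) and axonemal dyneins (Dnah, 10 of 11) were lower, as were guanylate-binding proteins (Gbp, 9 of 10) and the major histocompatibility family H2- (9 of 26), with adjusted p = 0.658 with an estimated correlation for each. Translation initiation factors (Eif, 27 of 51 higher), mitochondrial ribosomal proteins (Mrpl, 18 of 46), proteasome subunits (Psmd, 10 of 13) and the chaperonin Cct (7 of 8) were higher, again with adjusted p = 0.658 with an estimated correlation. These 8 families kept their direction under RLE and upper quartile scaling and after the length and GC correction. For Cfap that correction covered only 26 of 41 members (median change -1.38 log2 CPM), so it does not speak for the whole family.

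The tests of the next pattern were chosen after it was seen, and only for genomic DNA was the bound set before the value was seen. Of 4987 genes with 0 control counts, 425, 462, 918 and 1229 were detected in the naphthalene libraries. Controls hold 0 there by selection, so these numbers alone cannot show a gain in detection. Olfactory receptor genes, silent in most tissues, were not selected by their control counts. They were detected in 79 to 110 cases in controls and in 118, 133, 276 and 371 after naphthalene. Deeper sequencing is argued against, since at the depth of the shallowest library 856.3 more genes were detected after naphthalene (exact permutation p = 0.0286, the smallest possible). Counts per kb on X over autosomes were 1.22 (95% interval 0.904 to 1.60, against 0.5 for DNA of male mice). This argues against genomic DNA as the whole source for the 71.9% of silent genes with a length and position. Genes without them were not covered, and a part from genomic DNA stays open. Transcription running over from a raised neighbour stays open. The odds ratio of a raised neighbour for detected silent genes was 1.52 (1.07 to 2.15, Fisher p = 0.0162) over the 900 silent genes with a tested neighbour. For a lowered neighbour it was 0.978 (0.689 to 1.38, Fisher p = 0.932). Positions were known for only 78.1% of silent genes, so the neighbour check cannot decide. A limit of 80% coverage, which the genomic DNA and neighbour checks both miss, was applied only after their values had been seen.

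Several skeletal muscle transcripts stood out in naphthalene 1, with 995 counts of Acta1 and 943 of Myh8, against at most 27 and 2 in any other library. Ckm, Tnnt3 and Tnni2 were also highest there (314, 313 and 250 counts), although Ckm reached 85 in control 4. Mylpf did not stand out, with 2 counts in naphthalene 1.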
